A study of Mus musculus with 11 samples.

How the data were processed

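RNA bound to tagged ribosomes was sequenced from mouse ventral hippocampus. Per the labels, a retrograde virus carrying Cre recombinase was injected into the basomedial amygdala (BMA), lateral hypothalamus (LH), medial prefrontal cortex (mPFC) or nucleus accumbens (NAc) of a reporter line. In that line Cre switches on EGFP fused to the ribosomal protein L10a, so ventral hippocampal neurons whose axons reached the injected target carried the tag. Ribosomes were then pulled down from the hippocampus (translating ribosome affinity purification, TRAP), with 6 hippocampi in each sample per the series design text. Unpurified input RNA was not analysed here, so enrichment over whole tissue could not be measured. The labels do not say which animals went into which pool, so p-values measure the spread between these samples, part of which may be technical.

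The deposited gene table held raw read counts for 43432 Ensembl genes in 11 libraries, as whole numbers that were not normalized. Per the submitters' processing notes, STAR 2.5.2b and DESeq2 1.16.1 were used with the mouse build GRCm38, and the annotation release, the strand setting and the counting options are not given in the sources used here. A second deposited table gave the counts of reads left out of the gene counts, by reason, and a deposited mapping log gave reads, percentages and lengths per library. The gene counts plus ambiguous and off-gene reads equalled the uniquely mapped reads of the log, so reads with several mapping places were not counted by the authors. The authors' deposited table of all genes gave a log2 fold change, a p-value and an adjusted p-value for each pair of groups, and the GC content of each gene in percent. The same table held 22 columns of normalized values per library, which were not used here. Column names gave the group of each library and, for most, a number that does not follow the sample titles. Libraries are therefore named by group and by that number, or as unnumbered.

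Depth ran from 26021877 to 60595764 counted reads per library, with a median of 36687417. Reads were 50 bases long. Between 83.2% and 87.4% of reads mapped to 1 place, and between 9.78% and 13.6% mapped to too many places to be used. Counts on ribosomal protein genes and other families with near-identical pseudogenes are uncertain for that reason.

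Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by its default expression filter (21865 genes), libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 11 libraries together. The tests were an F test over the 4 groups, each group against the equally weighted mean of the other 3, and the 6 pairs. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Errors on log2 fold changes are standard errors (SE), taken as the size of the fold change over the square root of the F statistic, and bounds are at 95%. Levels are in CPM, counts scaled to the library size with TMM factors, given as mean ± SD. The common biological coefficient of variation was 49.5%.

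The 39 gene lists covered hippocampal fields, neighbouring regions, other cell types, ion channels, receptors, neuropeptides, adhesion and guidance molecules, transcription factors, and housekeeping machinery. They were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, two-sided. Adjustment ran over 156 pairs of list and group together. All list calls were lost when the correlation was estimated from the data, where the lowest adjusted p = 0.28, and with fry, where the lowest adjusted p = 0.345. Members were also tested adjusted over the list alone, which does not account for the number of lists and groups searched. Correlations across libraries were tested with 100000 random permutations, two-sided.

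The design, the tests, the lists, the alternative settings and the rule for named genes were fixed before the data were examined. The rule named, for each comparison, the genes with the largest changes past the adjusted threshold with an average log2 CPM of 1 or more. None passed. It also named the 6 genes with the smallest p over the 4 groups, the members of each list with the smallest p, the tagged gene Rpl10a, and sex-linked and mitochondrially encoded genes. Other named genes were chosen after their values were seen, and are marked so. Predicted genes and clones were counted and not named, and 1 gene that the rule named is not reported here.

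Alternative settings fixed beforehand were DESeq2 1.42.0, another library scaling, no filter on low counts, a stricter filter, the library number as a block, a fit of the compared pair alone, each library left out in turn, an estimated correlation and fry. Added after seeing the data were the share of reads outside genes as a covariate, a spline of each library on gene length and GC content with 5 degrees of freedom as offsets, both together, a comparison of BMA, LH and NAc each against the other groups but mPFC, and subtraction of a background estimated from 1329 olfactory and vomeronasal receptor genes. Gene lengths came from the GENCODE M21 annotation of GRCm38. On simulated data with 20429 genes, the test of mPFC against the other groups recovered 40% of 100 genes changed by 2-fold and 95% of 100 genes changed by 4-fold, with 12 false calls. For BMA against mPFC the shares were 12% and 90%, with 7 false calls. Genes were drawn independently there, unlike in the real libraries. With no list shifted, 0 of 156 simulated list tests were called. That simulation cannot show false calls among correlated genes, and the median estimated correlation in the real libraries was 0.18. Other splits of the real libraries gave a median of 38 list calls against the real 49, and 17 of 100 gave as many.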

Results

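The series asked whether ventral hippocampal neurons that project to different targets differ in the genes they express. RNA from tagged ribosomes was sequenced in 11 libraries: 3 from neurons projecting to the basomedial amygdala (BMA), 2 to the lateral hypothalamus (LH), 3 to the medial prefrontal cortex (mPFC) and 3 to the nucleus accumbens (NAc). Each library held 26021877 to 60595764 counted reads, and 21865 genes were tested. Levels are in CPM, which scales counts to the size of the library, and are given as mean ± SD.

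All 4 groups carried the transcripts of excitatory hippocampal neurons. Slc17a7, the vesicular glutamate transporter of these cells, stood at 1049 ± 41.2 CPM in BMA (n = 3), 1091 ± 248 in LH (n = 2), 1238 ± 131 in mPFC (n = 3) and 1276 ± 94.7 in NAc (n = 3). Camk2a, a kinase of excitatory synapses, lay between 1963 ± 650 in mPFC and 2389 ± 1301 in NAc. Glial and inhibitory transcripts were present too. Gfap, an astrocyte filament protein, lay between 223 ± 19.8 CPM in mPFC and 369 ± 10.9 in BMA, and Mbp, a myelin protein, between 1003 ± 254 in mPFC and 1882 ± 793 in BMA. Ttr, abundant in the choroid plexus, lay between 284 ± 143 CPM in NAc and 528 ± 160 in LH. Gad1, which makes GABA, stood at 962 ± 151 CPM in mPFC and 1645 ± 917 in BMA, while the vesicular GABA transporter Slc32a1 stood at 5.02 ± 1.20 in BMA and 8.18 ± 1.45 in mPFC. Over all libraries the interneuron genes Sst and Pvalb averaged 96.3 and 13.3 CPM. Why Gad1 stood so far above these genes was not tested, so its level is no measure of interneuron RNA. Rpl10a, the gene whose product carries the tag, was counted at 2.46 ± 0.483 CPM in LH to 3.38 ± 1.46 in mPFC. Its direction between groups changed with the settings and is not reported.

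Libraries differed most along an axis that crossed the projection groups. The share of uniquely mapped reads outside annotated genes ran from 4.58% in NAc 2 to 37.0% in the unnumbered BMA library. The first principal component, with 48.7% of the variance of log2 CPM, followed it (n = 11; r = 0.973, permutation p = 1e-05, adjusted p = 1.33e-05; rho = 0.945, permutation p = 3e-05, adjusted p = 4e-05). Leaving out the 2 libraries farthest from the median gave r = 0.961. Splice junctions per read went the other way (r = -0.989, permutation p = 1e-05; rho = -0.991, permutation p = 1e-05; r = -0.976 without those 2). Reads per kb in olfactory and vomeronasal receptor genes, which the hippocampus does not transcribe, also followed it (r = 0.986, permutation p = 1e-05; rho = 0.964, permutation p = 3e-05; r = 0.987 without those 2). The mitochondrially encoded share of counts did not pass (r = 0.075, permutation p = 0.854; rho = 0.482, permutation p = 0.138; r = -0.168 without those 2). These were 4 relations, and 1e-05 is the smallest p the permutations can give. The share averaged 17.2 ± 17.2% in BMA, 22.5 ± 8.81% in LH, 15.0 ± 6.35% in mPFC and 17.2 ± 13.6% in NAc, and did not differ between groups in an exact permutation test over 92400 arrangements (p = 0.923). The median correlation of log2 CPM was 0.958 between libraries of the same group and 0.965 between libraries of different groups. Each mPFC library stood alone at the end of a later component. These were mPFC 3 on the second (score -126, 13.0% of the variance), the unnumbered mPFC library on the third (110, 12.3%) and mPFC 2 on the fourth (-93.0, 6.99%).

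**Figure D1:**
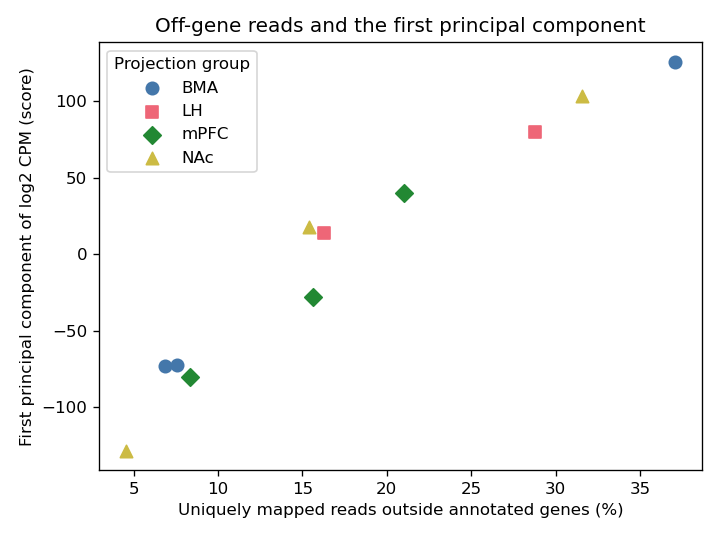
Score on the first principal component of log2 CPM (vertical) against the percentage of uniquely mapped reads outside annotated genes (horizontal); each point is 1 library, with color and shape for its projection group. The 3 BMA libraries lie at 6.89%, 7.55% and 37.0%, so libraries of the same group sit at both ends of the axis (r = 0.973 over 11 libraries).

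Across the 4 groups, Cdr1, Rpl41, Drap1, Rpl32, Mrps16 and Rps15 had the smallest p, and each stood highest in mPFC. None of them passed (edgeR adjusted p = 1 for each). Over all genes edgeR called 0, with 674 at an unadjusted p under 0.05, where 5% of the tested genes would be 1093. DESeq2 called 22, and edgeR without a filter on low counts called 82.

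The mPFC group had the most genes at an unadjusted p under 0.05 (1927), though 27 of 100 splits of the libraries gave as many. Cdr1, a brain transcript whose locus also makes a circular RNA, averaged 69.3 ± 23.2 CPM in mPFC (n = 3) against 20.1 ± 3.99 in BMA (n = 3), 20.5 ± 9.74 in LH (n = 2) and 25.1 ± 1.86 in NAc (n = 3). Its log2 fold change was 1.67 ± 0.23 (SE; 95% bounds 1.17 to 2.17), and 3 of 3 mPFC libraries lay above every other library. The gene (ENSMUSG00000090546) lies on chromosome X from 61183246 to 61185558 in GRCm38 and is protein-coding in the deposited annotation. It overlaps the antisense gene C230004F18Rik, and without a stated strand setting reads of the pair cannot be separated. Rpl41, a component of the large ribosomal subunit, had a log2 fold change of 1.22 ± 0.19 (38.8 ± 8.34 CPM in mPFC against 15.2 ± 4.96 in BMA), and Drap1, a transcriptional corepressor, 1.24 ± 0.21. Rpl41 (ENSMUSG00000093674) lies on chromosome 10 from 128548114 to 128549305. Drap1 (ENSMUSG00000024914), which overlaps 4930481A15Rik, lies on chromosome 19 from 5422805 to 5424979. Mrps16 of the mitochondrial ribosome stood at 0.87 ± 0.15 and Rps15 at 1.18 ± 0.21. Kdm8, a JmjC-domain protein chosen after its value was seen, went the other way at -1.37 ± 0.25, with 3.38 ± 1.05 CPM in mPFC and 9.48 ± 1.84 in NAc. Kdm8 (ENSMUSG00000030752) lies on chromosome 7 from 125444676 to 125462269. The edgeR adjusted p = 0.13 for each of these 6 genes.

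By count, edgeR called 0 genes in mPFC, with 1927 at an unadjusted p under 0.05, of which 1316 were higher and 611 lower. DESeq2 called 271 genes, 212 higher and 59 lower. Without a filter on low counts edgeR called 303, and without the unnumbered BMA library, whose off-gene share was the highest, it called 62.

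**Figure D2:**
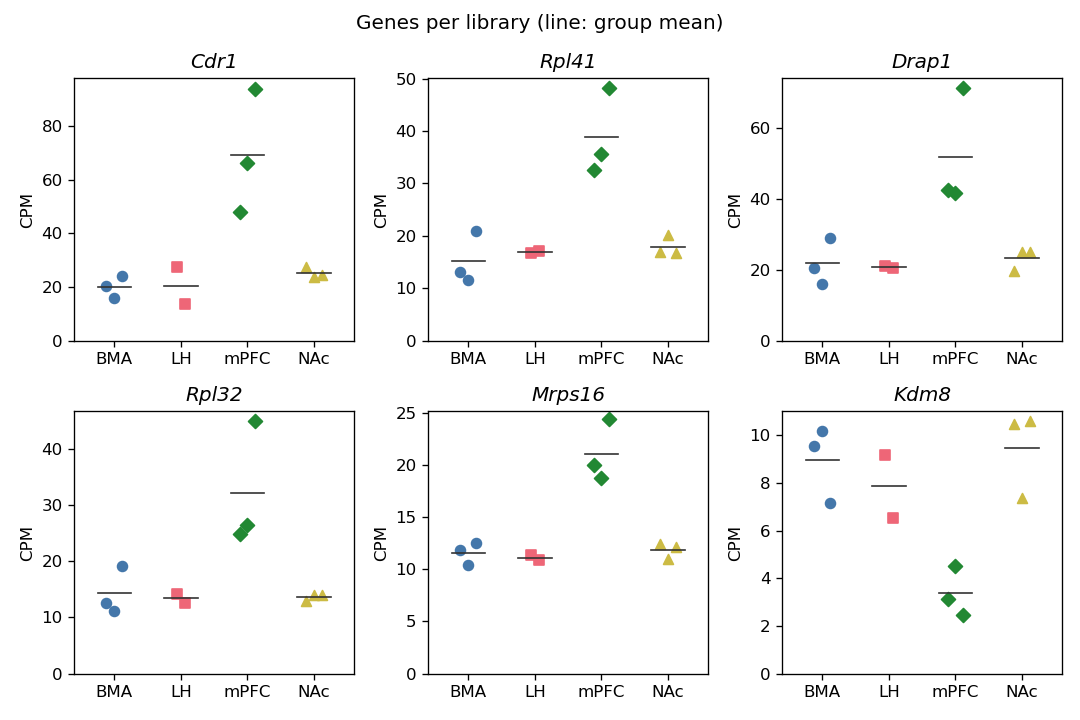
CPM per library (vertical, from 0) of Cdr1, Rpl41, Drap1, Rpl32, Mrps16 and Kdm8 in the 4 projection groups; each point is 1 library and each line a group mean. The 3 mPFC libraries lie above all others for the first 5 genes (Cdr1 mean 69.3 CPM) and below all others for Kdm8 (mean 3.38 CPM), with no p adjusted over all genes under 0.13.

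Genes of the protein synthesis and respiration machinery were higher together in mPFC. All 30 cytosolic ribosomal protein genes had a positive log2 fold change (median 0.67), and 19 of them passed adjusted over the list alone, against 0 over all genes. The list was higher by camera (adjusted p = 3.4e-21 and adjusted p = 0.42 with an estimated correlation). Rpl32 had a log2 fold change of 1.22 ± 0.21 (edgeR adjusted p = 0.0018 over the list alone, chromosome 6 from 115805505 to 115808747, overlapping Cand2), Rps9 0.93 ± 0.18 and Rps24 1.11 ± 0.24. These genes have many pseudogene copies, and reads that map to several places were not counted. The 3 mPFC libraries had the lowest uniquely mapped shares (83.2%, 84.0% and 84.2%, against 85.4% or more in the others), so a difference in library quality moves with this group. Of 30 nuclear-encoded oxidative phosphorylation genes, 23 were positive (median 0.56), and 16 passed adjusted over the list alone, against 0 over all genes. That list was higher by camera as well (adjusted p = 1.2e-11 and adjusted p = 0.42 with an estimated correlation), but its median was 0.28 without the unnumbered mPFC library. Ndufa2 and Ndufa5, subunits of complex I, had log2 fold changes of 0.95 ± 0.23 and 0.92 ± 0.23, and Cox5a of complex IV 0.86 ± 0.21.

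All 7 mitochondrially encoded genes tested had a positive log2 fold change in mPFC (median 1.37), and 5 passed adjusted over the list alone, against 0 over all genes. The list was higher by camera (adjusted p = 7.2e-05 and adjusted p = 0.68 with an estimated correlation). This rested on the unnumbered mPFC library, where these genes took 0.356% of the counts, the highest share of the 11 libraries. Without it the median was 0.10. mt-Nd6 averaged 29.0 ± 28.6 CPM in mPFC and 12.1 ± 8.05 in BMA (log2 fold change 1.38 ± 0.46). mt-Nd2 had a log2 fold change of 1.5 ± 0.51, with 1 of 3 mPFC libraries above the other group means.

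Activity-induced genes were higher in mPFC as a list. Of 13 immediate early genes, 11 were positive (median 0.35, camera adjusted p = 0.00016 and adjusted p = 0.67 with an estimated correlation), and 2 passed adjusted over the list alone, against 0 over all genes. These were Egr4, a zinc finger transcription factor induced by activity, at 66.8 ± 4.25 CPM in mPFC and 31.3 ± 0.381 in LH (log2 fold change 0.86 ± 0.18), and Ier2 at 0.91 ± 0.26. Junb stood at 0.63 ± 0.22. Without the mPFC 2 library the list median was 0.18. Of 22 neuropeptide genes, 18 were positive (median 0.36, camera adjusted p = 0.016 and adjusted p = 0.75 with an estimated correlation), with Sst at 0.76 ± 0.27, Cartpt at 0.86 ± 0.33 and Grp at 0.65 ± 0.27. Without the unnumbered mPFC library that median was -0.03 and the direction turned, and without mPFC 3 it was 0.69. Transcription factors of projection neurons had a median of 0.07 over 27 genes (camera adjusted p = 0.023 and adjusted p = 0.69 with an estimated correlation), with Nr2f1 at 0.50 ± 0.17 and Lmo4 at 0.57 ± 0.22. Without the LH 2 library it was 0.18.

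Matrix and adhesion genes were lower in mPFC as lists. Of 28 extracellular matrix genes, 23 were negative (median -0.28, camera adjusted p = 0.0056 and adjusted p = 0.67 with an estimated correlation). Acan, the core proteoglycan of perineuronal nets, averaged 1.28 ± 0.287 CPM in mPFC and 4.17 ± 1.61 in NAc (log2 fold change -1.32 ± 0.39), and Vcan stood at -0.73 ± 0.32. Cadherins, protocadherins and contactins were negative in 31 of 36 genes (median -0.21, camera adjusted p = 0.0016 and adjusted p = 0.69 with an estimated correlation), among them Cntn5 at -0.67 ± 0.22 and Cdh20 at -0.56 ± 0.21. Without the LH 3 library that median was -0.13. Axon guidance genes were negative in 43 of 56 (median -0.13, camera adjusted p = 0.025 and adjusted p = 0.70 with an estimated correlation), with Sema7a at -0.82 ± 0.23 and Ntn1 at -1.23 ± 0.38. Adjusted over the list alone, 0 genes of these 3 lists passed by edgeR, as over all genes, and 3, 6 and 6 stood at an unadjusted p under 0.05.

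Astrocyte and vascular genes were lower in mPFC as lists, while microglia genes, with a median of 0.22 (camera adjusted p = 0.25), were not called. The microglia median was -0.02 without the unnumbered mPFC library and 0.37 without mPFC 3. Astrocyte genes had a median of -0.40, with 10 of 14 negative (camera adjusted p = 0.024 and adjusted p = 0.42 with an estimated correlation), and the water channel Aqp4 stood at -0.56 ± 0.20 and the bicarbonate transporter Slc4a4 at -0.41 ± 0.18. Endothelial and mural genes were negative in 12 of 12 (median -0.23, camera adjusted p = 0.0053 and adjusted p = 0.69 with an estimated correlation), with Vtn at -0.71 ± 0.22, but the median was 0.01 without the unnumbered mPFC library and -0.95 without mPFC 2. In lists without a camera call in mPFC, 4 genes passed adjusted over the list alone by edgeR. These were the synaptic calmodulin-binding protein Nrgn (1.31 ± 0.29; 277 ± 170 CPM in mPFC, 109 ± 13.9 in NAc), the interneuron protein Pvalb (1.03 ± 0.23), the mitochondrial chaperonin Hspe1 (1.0 ± 0.25) and the zinc finger repressor Trps1 (-0.58 ± 0.16). Hspe1 overlaps Hspd1. None of these 4 passed adjusted over all genes (edgeR adjusted p = 0.14, 0.14, 0.17 and 0.21). Neurod2 (0.51 ± 0.18), the neuregulin receptor Erbb4 (-0.59 ± 0.20) and Htr4 (-0.87 ± 0.25) passed neither over the list alone nor over all genes (edgeR adjusted p = 0.37, 0.30 and 0.22 over all genes).

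The NAc libraries had higher levels of axon guidance and receptor genes as lists, with small changes per gene. Of 100 splits of the libraries, 17 gave as many called lists as the real 13. Of 56 axon guidance genes, 50 were positive (median 0.27, camera adjusted p = 4.9e-19 and adjusted p = 0.28 with an estimated correlation). Slit3, a secreted guidance cue, averaged 49.8 ± 10 CPM in NAc (n = 3) and 32.8 ± 2.64 in BMA (log2 fold change 0.50 ± 0.16), and the semaphorin receptor subunit Plxna4 stood at 0.49 ± 0.19. Of 24 glutamate receptor genes, 23 were positive (median 0.23, camera adjusted p = 3e-11 and adjusted p = 0.28 with an estimated correlation), with the NMDA receptor subunit Grin2a at 0.70 ± 0.21 and the kainate receptor subunit Grik4 at 0.36 ± 0.16. Cadherins, protocadherins and contactins were positive in 33 of 36 (median 0.22, camera adjusted p = 7.6e-11 and adjusted p = 0.42 with an estimated correlation), with Pcdh8 at 0.56 ± 0.26 and Cntn2 at 0.43 ± 0.21. Matrix genes were positive in 26 of 28 (median 0.22, camera adjusted p = 5.5e-09 and adjusted p = 0.28 with an estimated correlation), with Acan at 0.94 ± 0.34 and Tnr at 0.49 ± 0.21. Without the NAc 2 library the matrix median was 0.34. Against BMA and LH alone, the axon guidance median was 0.18 (camera adjusted p = 6.5e-18 and adjusted p = 0.12 with an estimated correlation), and all 4 lists were called again. These lists were also called as lower in BMA, and all but the glutamate receptors in mPFC. Each group is part of the mean that the others are compared with, so these calls are not independent. Lists were not tested in NAc against BMA directly.

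Ion channel and modulatory receptor lists were higher in NAc as well. Sodium and calcium channel genes were positive in 20 of 23 (median 0.21, camera adjusted p = 3.6e-06 and adjusted p = 0.28 with an estimated correlation), with Cacna2d2 at 0.53 ± 0.27 and Cacna1d at 0.32 ± 0.17. Potassium and HCN channel genes had a median of 0.13 (camera adjusted p = 0.00011 and adjusted p = 0.67 with an estimated correlation), and of 0.08 without the unnumbered NAc library. Monoamine and acetylcholine receptors had a median of 0.13 (camera adjusted p = 9.4e-05 and adjusted p = 0.67 with an estimated correlation), with the serotonin receptor Htr4 at 0.49 ± 0.23 and the nicotinic subunit Chrna7 at 0.39 ± 0.18. Without the NAc 3 library that median was 0.04, and without NAc 2 0.23. Neuropeptide receptors had a median of 0.07 (camera adjusted p = 0.0058 and adjusted p = 0.69 with an estimated correlation), with Trhr at 0.48 ± 0.22, and GABA receptors 0.11 (camera adjusted p = 0.037 and adjusted p = 0.74 with an estimated correlation), with Gabbr2 at 0.38 ± 0.32. Oligodendrocyte precursor genes had a median of 0.21 (camera adjusted p = 0.025 and adjusted p = 0.42 with an estimated correlation), with Pdgfra at 0.45 ± 0.19. Without the LH 2 library the precursor median was 0.10, without mPFC 3 the neuropeptide receptor median was 0.00, without mPFC 2 it was 0.17, and without the unnumbered BMA library the GABA receptor median was 0.04. Against BMA and LH alone, neuropeptide receptors (median 0.05, camera adjusted p = 0.15) and GABA receptors (median 0.04, camera adjusted p = 0.20) were not called.

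Transcription factors of projection neurons were lower in NAc as a list. They had a median of -0.11 (camera adjusted p = 0.025 and adjusted p = 0.70 with an estimated correlation), with Id2 at -0.39 ± 0.23, and of -0.03 without the NAc 3 library. Against BMA and LH alone the median was -0.04 and was not called (camera adjusted p = 0.45). No gene of any NAc list passed adjusted over the list alone. Over all genes edgeR called 0 and DESeq2 0. Against 1093 expected with no difference, 119 stood at an unadjusted p under 0.05 by edgeR, 90 of them higher. Among these, chosen after their values were seen, were the laminin subunit Lamc1 (0.57 ± 0.17) and the protocadherin Pcdhb8 (0.67 ± 0.21).

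**Figure D3:**
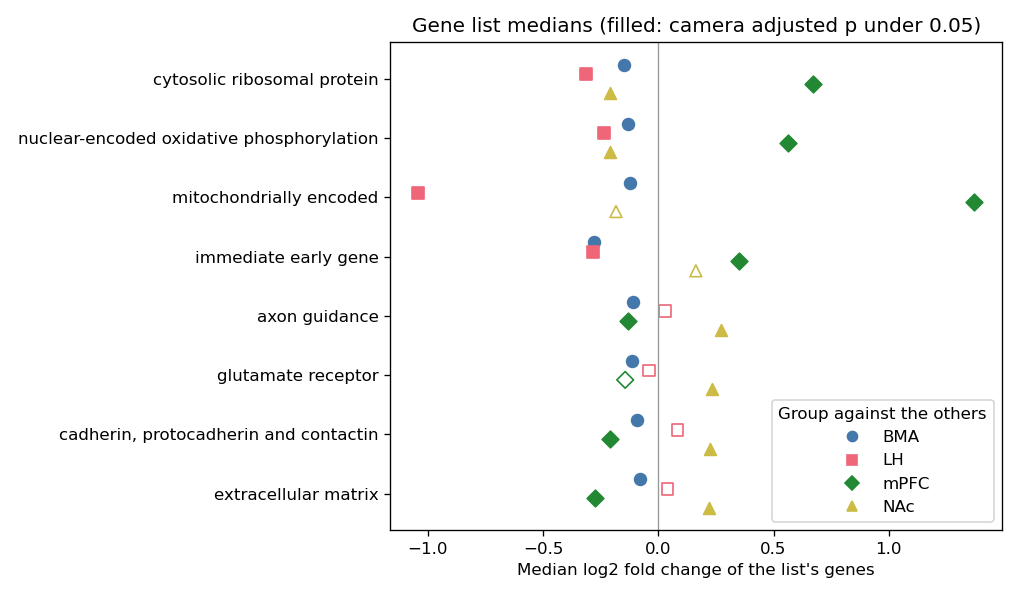
Median log2 fold change (horizontal) of 8 gene lists in each projection group against the other 3; filled symbols had a camera adjusted p under 0.05 with a preset correlation, and none had with an estimated correlation. The mPFC medians lie to the right for ribosomal protein (0.67) and oxidative phosphorylation genes (0.56), and the NAc medians for axon guidance (0.27) and glutamate receptor genes (0.23).

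The BMA libraries had lower levels of activity-induced and signalling genes as lists, though 15 of 100 splits of the libraries gave as many called lists as the real 15. Of 13 immediate early genes, 12 were negative (median -0.28, camera adjusted p = 5.3e-07 and adjusted p = 0.58 with an estimated correlation), with Btg2 at -0.40 ± 0.21. Egr4 stood at -0.40 ± 0.19, with 0 of 3 BMA libraries below the other group means, as its level in BMA (34.8 CPM) lay above that in LH (31.3). Of 22 neuropeptide genes, 20 were negative (median -0.22, camera adjusted p = 0.00011 and adjusted p = 0.69 with an estimated correlation), with Vgf, a secretory granule protein, at -0.51 ± 0.23 and Grp at -0.54 ± 0.29. Axon guidance genes were negative in 43 of 56 (median -0.11, camera adjusted p = 4.1e-09 and adjusted p = 0.42 with an estimated correlation), with Sema3f at -0.85 ± 0.44 and Efnb3 at -0.40 ± 0.21. Sodium and calcium channels (camera adjusted p = 9.4e-05 and adjusted p = 0.42 with an estimated correlation) and glutamate receptors (camera adjusted p = 0.00022 and adjusted p = 0.58 with an estimated correlation) each had a median of -0.11, with Cacna1g at -0.26 ± 0.18 and Grin2d at -0.34 ± 0.25. Against LH and NAc alone these 5 lists were called again (lowest adjusted p = 0.12 with an estimated correlation), with a median of -0.13 for immediate early genes, -0.09 for neuropeptides and -0.19 for axon guidance genes. NAc is part of this mean too. The calls of axon guidance genes, glutamate receptors and sodium and calcium channels are therefore not independent of those as higher in NAc. Without BMA 3 the medians were -0.23 for axon guidance, -0.23 for glutamate receptors, -0.17 for sodium and calcium channels and -0.10 for neuropeptides, and without BMA 2 -0.47 for immediate early genes, which stood at -0.17 without LH 2.

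Further BMA lists were called with smaller medians. Cadherins stood at -0.09 (camera adjusted p = 0.00013 and adjusted p = 0.69 with an estimated correlation) with Cntn2 at -0.34 ± 0.21. Monoamine and acetylcholine receptors stood at -0.08, with 21 of 34 negative (camera adjusted p = 0.0016 and adjusted p = 0.69 with an estimated correlation) and Adra1d at -0.42 ± 0.20. Matrix genes stood at -0.08 (camera adjusted p = 0.0024 and adjusted p = 0.67 with an estimated correlation) with Col19a1 at -0.47 ± 0.24. Neuropeptide receptors stood at -0.11, with 18 of 29 negative (camera adjusted p = 0.047 and adjusted p = 0.74 with an estimated correlation) and Tacr1 at -0.57 ± 0.31. Genes of the ventral hippocampal pole stood at -0.15 (camera adjusted p = 0.014 and adjusted p = 0.67 with an estimated correlation). GABA interneuron genes stood at -0.10 (camera adjusted p = 0.035 and adjusted p = 0.67 with an estimated correlation) with Slc32a1 at -0.56 ± 0.21. Of these genes 9 of 14 were negative, and the average of Gad1 was highest in BMA (1645 CPM). Against LH and NAc alone the medians were -0.19 for cadherins, -0.13 for monoamine and acetylcholine receptors, -0.21 for matrix genes and -0.25 for the ventral pole, all called again (lowest adjusted p = 0.13 with an estimated correlation), and -0.03 for GABA interneurons, which were not called (camera adjusted p = 0.12). The cadherin, matrix and both receptor lists were called as higher in NAc, so these calls are not independent of those either. Without BMA 3 the medians were -0.19 for cadherins and -0.24 for matrix genes, and without the LH 3 library the matrix median was -0.03. Without NAc 2 they were -0.15 for monoamine and acetylcholine receptors and -0.19 for neuropeptide receptors, which stood at -0.03 without the unnumbered mPFC library. Without BMA 2 the ventral pole median was -0.28.

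Interferon response genes were higher in BMA, with 11 of 12 positive (median 0.25, camera adjusted p = 0.039 and adjusted p = 0.69 with an estimated correlation). Gbp2, an interferon-induced GTPase, averaged 3.11 ± 0.829 CPM in BMA (n = 3) and 1.33 ± 0.239 in mPFC (log2 fold change 0.80 ± 0.30). Without the unnumbered mPFC library the list median was 0.13 and without LH 2 0.41, and against LH and NAc alone it was 0.26 and was not called (camera adjusted p = 0.16). The astrocyte gene Gfap stood at 0.49 ± 0.21, while the astrocyte list was not called. For Gfap 3 of 3 BMA libraries lay above every other library, but the lowest barely so (356.6 CPM against 356.2 in a NAc library). No gene of any BMA list passed adjusted over the list alone. Over all genes edgeR called 0 and DESeq2 0. Against 1093 expected with no difference, 126 stood at an unadjusted p under 0.05 by edgeR, 113 of them higher. That lean was smaller in other settings: a stricter filter on low counts gave 35 higher and 32 lower, the library number as a block 143 higher and 103 lower, and the off-gene share as a covariate 196 higher and 175 lower. Among the 126, chosen after their values were seen, were Zfp62 (0.54 ± 0.16) and Gpr162 (-0.53 ± 0.19). Several BMA medians depended on the unnumbered BMA library, which had the highest off-gene share. Without it the median was -0.03 for glutamate receptors, -0.04 for sodium and calcium channels, -0.03 for cadherins, where the test turned, 0.07 for the ventral pole, 0.01 for GABA interneurons and -0.45 for neuropeptides.

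In LH 10 lists were called, and 56 of 100 splits of the libraries gave as many. The LH libraries (n = 2) held more RNA of meningeal and vascular genes as lists. These genes mark cells other than the tagged neurons, and expression by the neurons was not tested. All 8 meningeal fibroblast genes were positive (median 0.47, camera adjusted p = 3.6e-05 and adjusted p = 0.58 with an estimated correlation). Slc22a6, an organic anion transporter, averaged 6.02 ± 0.508 CPM in LH (n = 2) and 1.76 ± 0.711 in mPFC (log2 fold change 0.99 ± 0.45), and the matrix protein Lum stood at 0.54 ± 0.36, which turned to -0.02 with length and GC offsets. Endothelial and mural genes were positive in 11 of 12 (median 0.21, camera adjusted p = 0.0026 and adjusted p = 0.69 with an estimated correlation), with Vtn at 0.51 ± 0.24. Without the mPFC 2 library that median was 0.64, and against BMA and NAc alone it was 0.11 and was not called (camera adjusted p = 0.062). Neuropeptide receptors were positive in 24 of 29 (median 0.08, camera adjusted p = 0.0069 and adjusted p = 0.69 with an estimated correlation), with Npy5r at 0.44 ± 0.22, but the median was -0.04 without the LH 3 library and 0.28 without LH 2. The neuropeptide gene Nts stood at 0.82 ± 0.34 and turned to -0.08 with length and GC offsets.

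Activity and stress response lists were lower in LH. All 13 immediate early genes were negative (median -0.28, camera adjusted p = 0.0027 and adjusted p = 0.69 with an estimated correlation), with Egr4 at -0.60 ± 0.22, and the median was -0.02 without the LH 3 library and -0.60 without LH 2. All 7 mitochondrially encoded genes were negative (median -1.04, camera adjusted p = 5.2e-05 and adjusted p = 0.67 with an estimated correlation), with mt-Nd5 at -1.04 ± 0.56, and the median was -0.63 without the unnumbered mPFC library and -0.69 against BMA and NAc alone (camera adjusted p = 0.0066 and adjusted p = 0.71 with an estimated correlation). Heat shock and unfolded protein genes stood at -0.18 (camera adjusted p = 0.0036 and adjusted p = 0.69 with an estimated correlation) with Ddit3 at -0.38 ± 0.21. Excitatory neuron genes stood at -0.17 (camera adjusted p = 0.033 and adjusted p = 0.69 with an estimated correlation) with Neurod2 at -0.31 ± 0.22. Microglia genes stood at -0.16 (camera adjusted p = 0.029 and adjusted p = 0.73 with an estimated correlation) with Aif1 at -0.74 ± 0.50. Without LH 3 the heat shock median was 0.01 and the excitatory neuron median 0.00, and without LH 2 the microglia median was 0.05 and the test turned. Without LH 2 the heat shock median was -0.50 and the excitatory neuron median -0.44, and without LH 3 the microglia median was -0.41. Against BMA and NAc alone, immediate early genes (median -0.10, camera adjusted p = 0.15), excitatory neuron genes (median -0.17, camera adjusted p = 0.13) and microglia genes (median -0.13, camera adjusted p = 0.057) were not called.

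No gene of any LH list passed adjusted over the list alone. Over all genes edgeR called 0 and DESeq2 0. Against 1093 expected with no difference, 85 stood at an unadjusted p under 0.05 by edgeR, 57 of them higher. Among these, chosen after their values were seen, were Vstm4 (0.90 ± 0.25) and Msantd1 (-1.10 ± 0.35), which overlaps Htt.

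Ribosomal protein and oxidative phosphorylation genes were also called as lower in BMA, LH and NAc in comparisons whose mean included mPFC. Rps9, of the small ribosomal subunit, stood at 22.5 ± 5.74 CPM in BMA, 21.5 ± 1.40 in LH and 23.7 ± 0.373 in NAc, against 43.0 ± 9.93 in mPFC. Cox5a stood at 54.2 ± 8.85 CPM in BMA, 50.2 ± 10.5 in LH and 50.6 ± 3.19 in NAc, against 93.4 ± 33.6 in mPFC. With mPFC in the comparison, the ribosomal protein median was -0.15 in BMA (camera adjusted p = 1.2e-05 and adjusted p = 0.69 with an estimated correlation), -0.32 in LH (camera adjusted p = 1.7e-09 and adjusted p = 0.67 with an estimated correlation) and -0.21 in NAc (camera adjusted p = 1.1e-05 and adjusted p = 0.69 with an estimated correlation). With mPFC left out it was 0.05, -0.11 and -0.00, and none was called (camera adjusted p = 0.41, 0.064 and 0.41), though 21 of 30 genes stayed negative in LH. The oxidative phosphorylation median was -0.13 in BMA (camera adjusted p = 0.0036 and adjusted p = 0.69 with an estimated correlation), -0.24 in LH (camera adjusted p = 1.2e-05 and adjusted p = 0.67 with an estimated correlation) and -0.21 in NAc (camera adjusted p = 7.3e-05 and adjusted p = 0.67 with an estimated correlation). With mPFC left out it was 0.09, -0.07 and -0.04, and none was called (camera adjusted p = 0.37, 0.24 and 0.97). Mitochondrially encoded genes had a median of -0.12 in BMA (camera adjusted p = 0.022 and adjusted p = 0.74 with an estimated correlation), and of 0.34 with mPFC left out (camera adjusted p = 0.90). That median ran from -1.0 without the unnumbered BMA library to 0.28 without the unnumbered mPFC library. Leaving out 1 library, the ribosomal protein median ran from -0.42 to -0.04 in BMA and from -0.47 to -0.18 in LH. The oxidative phosphorylation median ran from -0.22 to -0.04 in BMA, from -0.34 to -0.12 in LH and from -0.26 to -0.11 in NAc.

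Apart from the ventral pole in BMA, lists of hippocampal fields and neighbouring regions were not called in any group. The largest medians were 0.08 in NAc and -0.08 in BMA for the dorsal pole, 0.11 in NAc for CA1, -0.16 in LH for CA2, -0.07 in LH for CA3, -0.24 in mPFC for dentate granule cells and 0.21 in LH for the subiculum. They were 0.24 in BMA for the thalamus, -0.10 in BMA for striatal and amygdalar projection neurons and -0.09 in mPFC for neocortical and entorhinal layers. Several shrank or turned when 1 library was left out. The subiculum median in LH was -0.12 without LH 3 and 0.45 without LH 2. The dentate median in mPFC was -0.09 without NAc 2, and the thalamus median in BMA 0.11 without LH 3. The lowest camera adjusted p among these uncalled lists was 0.13, for the subiculum and for the thalamus, both in BMA. Oligodendrocyte genes (-0.06 in NAc), choroid plexus and ependyma genes (-0.31 in NAc), reactive astrocyte genes (0.14 in BMA), synaptic vesicle genes (0.07 in NAc) and sex-linked genes (-0.78 in mPFC) were not called either, with a lowest camera adjusted p of 0.10. Xist, the non-coding RNA of the inactive X chromosome, had a log2 fold change of -1.78 ± 0.82 in mPFC (edgeR adjusted p = 0.56) and 1.68 ± 0.75 in LH (edgeR adjusted p = 1).

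Between pairs of groups, more genes stood at an unadjusted p under 0.05 where the mPFC was 1 of the pair, with 0 called by edgeR in each of the 6 pairs. Those counts lay little above 5% of the tested genes. Of 10 splits, the real one included, 5 gave as many for BMA against mPFC and 4 for mPFC against NAc. In BMA against mPFC, 1289 genes stood at an unadjusted p under 0.05, and DESeq2 called 12. Chosen after their values were seen, Cdr1 had a log2 fold change of -1.78 ± 0.30, Rpl41 -1.35 ± 0.25, Kdm8 1.40 ± 0.29 and the zinc finger gene Zfp62 0.98 ± 0.20 (edgeR adjusted p = 0.58 for each). In LH against mPFC, 1130 genes stood at an unadjusted p under 0.05, and DESeq2 called 3. Cdr1 stood at -1.76 ± 0.35, the collagen receptor Ddr2 at 1.2 ± 0.26 and Egr4 at -1.09 ± 0.26 (edgeR adjusted p = 0.87 for each). In mPFC against NAc, 1275 genes stood at an unadjusted p under 0.05, and DESeq2 called 2. Kdm8 stood at -1.49 ± 0.29, Cdr1 at 1.46 ± 0.30 and Rpl32 at 1.23 ± 0.27 (edgeR adjusted p = 0.71 for each).

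The 3 pairs without the mPFC had few genes. At an unadjusted p under 0.05 there were 12 for BMA against LH, 59 for BMA against NAc and 36 for LH against NAc, and DESeq2 called 0 in each. With no difference between groups, 1093 genes would be expected at that p. Counts so far below it mean that the p-values ran too high, so they are no evidence that these groups are alike. With the off-gene share as a covariate the counts were 95, 307 and 169, still below 1093. The cause was not tested. Also chosen after their values were seen, Perp (-0.91 ± 0.31) and Msantd1 (1.07 ± 0.39) were among the 12. Slit3 (-0.60 ± 0.20) and the lipid transporter Abca2 (-0.73 ± 0.27) were among the 59, and Pcdhb8 (-0.85 ± 0.29) and the matrix protein Thbs4 (-0.98 ± 0.35) among the 36. The edgeR adjusted p = 1 for each of these 6 values.

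The authors' deposited table named genes in the same 3 pairs that include the mPFC. At an adjusted p under 0.05, the authors' deposited table held 23 genes for BMA against mPFC, 12 higher and 11 lower in BMA. It held 3 for LH against mPFC (Slc16a12, Kbtbd13 and Cdr1), 1 for mPFC against NAc (Kdm8) and 0 for the other pairs. Cdr1 had a log2 fold change of -1.80 in the authors' deposited table for BMA against mPFC (adjusted p = 0.00034), and Kdm8 -1.49 for mPFC against NAc (adjusted p = 0.025). All 27 entries had the same sign and an unadjusted p under 0.05 in edgeR here, and none had an adjusted p under 0.575. In DESeq2 here, 12 of the 23, 3 of the 3 and 1 of the 1 passed.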

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

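The test with nuclear-retained transcripts was chosen after the level of Xist had been seen to follow the share of reads outside genes; the other tests in this part were written down before their results. That share is a read class outside the gene counts, and it stood above 0 in every library. Of the uniquely mapped reads it took 6.89% in the BMA 2 library, 7.55% in BMA 3 and 37.0% in the unnumbered BMA library. It took 16.3% in LH 2 and 28.8% in LH 3. It took 21.0% in mPFC 2, 15.7% in mPFC 3 and 8.36% in the unnumbered mPFC library. It took 4.58% in NAc 2, 31.5% in NAc 3 and 15.4% in the unnumbered NAc library.

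The share spread more widely within projection groups than between them. The ratio of mean squares was 0.146, which met the bound set beforehand against the projection target as its main source. With so few libraries in each group, a difference between targets could have been missed. Genomic DNA and unspliced nuclear RNA remained open, since reads per kb in 1329 silent receptor genes rose with off-gene reads per kb with a slope of 0.255 ± 0.011 (SE), between the bounds of 0.1 for nuclear RNA alone and 0.5 for DNA alone. Malat1, Neat1, Meg3, Miat, Rian, Mirg, Snhg11 and Kcnq1ot1, non-coding transcripts largely held in the nucleus, all had higher log2 CPM where the share was higher, with a median slope of 0.83 per 10 percentage points (95% bootstrap interval 0.35 to 0.87 over genes). That median exceeded those of all 10000 random lists matched on expression, whose median was -0.08. Such a slope was not rare for single genes, as 14.4% of all tested genes had one as large. The slopes of these transcripts ran from 0.28 (Rian) and 0.35 (Malat1) to 1.05 (Kcnq1ot1). The bootstrap interval over genes does not measure the spread between libraries. A candidate explanation is that the purifications carried different amounts of nuclear RNA, with DNA as a possible further source, and neither was measured directly.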

How the results depend on the processing

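The covariate, offset and background settings and the comparison without mPFC were chosen after seeing the data. With the library number as a block, edgeR called 0 genes in every comparison and 48 list results, against 49 without it. Unnumbered libraries were 1 block. Of 12 pairs of libraries with the same number, 4 had deviations correlated above 0.1 (range -0.61 to 0.65), and of 3 unnumbered pairs 1 had. No common pairing by number was seen. These deviations also carry the axis that followed the off-gene share, so they cannot exclude shared pools or batches.

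Against the main count of 0 genes, DESeq2 called 22 over the 4 groups, 271 for mPFC, 12 for BMA against mPFC, 3 for LH against mPFC and 2 for mPFC against NAc. Without a filter on low counts edgeR called 82 over the 4 groups, 3 for BMA, 2 for LH, 303 for mPFC, 88 for BMA against mPFC, 19 for LH against mPFC and 23 for mPFC against NAc. All 303 also passed the filter used in the main test, but the added low genes enter the shared dispersion estimates and remain a possible cause. For mPFC the covariate gave 128 genes, covariate and offset together 103, and leaving out 1 library 0 to 62, with 62 when the unnumbered BMA library was left out. The causes were not tested. Of the 271 genes from DESeq2, 109 were shared with the covariate and 167 with the unfiltered test. List results numbered 0 with an estimated correlation, 0 with fry and 35 to 53 in the other settings with all libraries.

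The other 233 counts stayed within 1.5 times the main count. For the fold changes of named genes given here, 2162 values kept their direction and side of the threshold, 86 kept their direction and passed it, and 2 turned. Rpl10a, whose direction changed with the settings, was not in this count. With the length and GC offset the value went to -0.0175 for Lum, LH against the other groups, and to -0.0810 for Nts, LH against the other groups. That offset moved the median log2 fold change of all genes from -0.02 to -0.13 in LH and from -0.06 to 0.09 in mPFC, where genes at an unadjusted p under 0.05 split into 1528 higher and 394 lower, against 1316 and 611. For lists, 789 values kept their call, 171 lost it and 9 turned. Leaving out 1 library, the median ran from -0.19 to -0.0270 for cadherins in BMA, from -0.41 to 0.0546 for microglia in LH, from -0.60 to -0.0186 for immediate early genes in LH and from -0.0292 to 0.69 for neuropeptides in mPFC. Against the other groups but mPFC, the test turned for 4 lists: the median was 0.0934 for oxidative phosphorylation and 0.0515 for ribosomal protein genes in BMA, and -0.0404 and -0.00430 in NAc. Of the lists called with mPFC, 10 of 15 stayed called in BMA, 4 of 10 in LH and 8 of 13 in NAc. Why the other calls were lost was not tested. With covariate and offset, immediate early genes in LH had a median of -0.0511 and the test turned. The causes of the other turns were not tested.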

Other observations

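All tests in this part on gene families, on genes at an unadjusted p, on the covariate and on leaving out the unnumbered mPFC library were chosen after results had been seen. The tests of length, GC content, off-gene share and other splits of the lists were written down before.

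Whole families of ribosomal and respiratory genes were picked by symbol after the lists had been seen, and were not tested for enrichment over all genes. By symbol, 74 of 76 cytosolic ribosomal protein genes had a positive log2 fold change in mPFC against the other groups (median 0.81), as had 73 of 77 mitochondrial ribosomal protein genes (median 0.47) and 88 of 98 genes of respiratory chain complexes and ATP synthase (median 0.67). Without the unnumbered mPFC library these medians were 0.60, 0.28 and 0.35. Apart from list members, 44 of 46 cytosolic ribosomal protein genes (median 0.89) and 67 of 71 respiratory genes (median 0.68) were positive. In edgeR 0 of the families' genes passed the adjusted threshold, and 47, 42 and 61 were higher at an unadjusted p under 0.05. With DESeq2, 21, 7 and 21 of them passed as higher and 0 as lower. With the share of off-gene reads as a covariate in edgeR, 10, 4 and 13 passed as higher and 0 as lower.

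With that covariate, 128 genes passed in mPFC, 105 higher and 23 lower, and 0 in BMA, LH and NAc by edgeR, which had 371, 314 and 422 genes at an unadjusted p under 0.05 there and for which DESeq2 without the covariate gave 0. Cdr1 had a log2 fold change of 1.64 under the covariate, Rpl41 1.30, Rpl32 1.26, Nrgn 1.33, Egr4 0.83 and Kdm8 -1.41, and all 6 passed. Of 5 sex-linked genes Ddx3y also passed as lower (-1.18 ± 0.23, edgeR adjusted p = 0.043). The other Y-linked genes stood at -0.92 ± 0.35 (Kdm5d), -0.53 ± 0.43 (Uty) and -0.003 ± 0.21 (Eif2s3y). Xist was lower too (-1.08 ± 0.42, edgeR adjusted p = 0.22). A different sex make-up of the pools remained open, though fewer males would not by themselves leave Eif2s3y unchanged or lower Xist. Only 2 of 100 splits of the libraries gave as many genes, the real one included. The other one gave 226 and also kept the 3 mPFC libraries together, so splits that broke up that group gave fewer. That share lay under 0.05, but the covariate was 1 of several settings and was chosen after results had been seen. The splits therefore cannot exclude chance for this count. As the covariate was chosen on these libraries, a difference of mPFC-projecting neurons remains a hypothesis, and an unrecorded preparation batch that held the 3 mPFC libraries, which had the lowest uniquely mapped shares (83.2% to 84.2%), may equally lie behind it.

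The ribosomal protein and oxidative phosphorylation lists were higher in mPFC, and 43 of 100 splits gave as many lists past the threshold as the real 11, with 21 the highest of the others, so chance was not excluded for the number of lists. A trend on gene length and GC content was excluded as the whole cause, since the lower of both list medians was 1.12 times its uncorrected value with the offsets. The offsets also raised the median of all genes in mPFC. The ratio includes that shift and does not exclude the trend as a part of the cause. The off-gene share was excluded as the whole cause by the same bound, at 1.05 times. Without the unnumbered mPFC library the ribosomal protein median kept 0.784 of its value (0.67 to 0.52), which excludes that library as the whole source. The oxidative phosphorylation median kept 0.490 (0.56 to 0.28, bootstrap interval 0.373 to 0.665), so whether that library may be the main source stayed open. A bound first written for both lists together, before this result, was therefore not decided. The bounds for each list alone were written afterwards.

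The axon guidance, glutamate receptor and cadherin lists were higher in NAc, and 17 of 100 splits gave as many lists as the real 13, with 20 the highest of the others, so chance was not excluded. The lowest of the 3 medians kept 0.732 of its value with the length and GC offsets (axon guidance) and 0.966 with the covariate (glutamate receptor), which excludes either trend as the whole cause. The same lists were called as lower in BMA, and each of these groups is part of the other's mean. Whether they reflect only a difference between NAc and BMA was not tested. A difference of NAc-projecting neurons stayed untested beyond this.

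For genes at an unadjusted p under 0.05, chance was not excluded in BMA, mPFC or NAc against the others, and LH was not tested. For BMA, 91 of 100 splits gave as many as the real 126, and the highest other gave 7565. For mPFC, 27 of 100 gave as many as 1927, and the highest other gave 7919. For NAc, 83 of 100 gave as many as 119, and the highest other gave 7315. Splits with so many genes point to a structure of the libraries that crosses the projection groups. Pairs of groups allow 10 splits, too few for a share under 0.05. BMA against mPFC gave 1289 genes, with 5 splits as large and 4627 the highest other. BMA against NAc gave 59, with 8 as large and 8333 the highest other, and mPFC against NAc gave 1275, with 4 as large and 1935 the highest other.

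Xist, the non-coding RNA of the inactive X chromosome, ranged from 0.96 to 37.8 CPM over the libraries, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were counted in all 11. Xist had a slope of 1.22 in log2 CPM per 10 percentage points of off-gene reads.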
